A study of Homo sapiens with 8 samples.

How the data were processed

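Gene expression and guide RNA libraries were made from the same 4 GEM groups of a 10x Genomics 3' assay with feature barcoding, per the labels' protocols. Each GEM group was loaded with 20000 cells, dCas9 was delivered 3 days before the guides, and cells with both reporters were sorted 9 days after the guides. The deposited matrices hold UMI counts per feature and cell barcode, made with Cell Ranger 7.0.0 on GRCh38, per the submitters' processing notes. The values are raw counts per the file headers, with 36601 gene features, a dCas9 feature and 132 guides in 1 matrix per GEM group. No normalization of the deposited counts was recorded, and none was undone. The 4 gene expression and 4 guide libraries were grouped by the titles in the labels.

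Cells were kept with at least 1000 gene UMIs and at most 20% mitochondrial UMIs. A doublet caller was not run and no correction for free RNA was made. Genes on chromosome Y and XIST and TSIX, 111 features, were left out of all tests. Gene positions were taken from GENCODE 29 on GRCh38, which held 34616 of the features. Guide sequences were matched to the transcript sequences of that annotation, which placed 12 of 132 guides, so genes within a window around the enhancer and variant elements could not be listed and only the named pairs and, in the matched comparison, other genes within 1 Mb of the named genes were tested as cis pairs.

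The choices of design were made before the data were examined: cells would be assigned to 1 target (at least 5 UMIs and 80% of guide UMIs) if at least 50% of the cells with guide UMIs were so assigned, and otherwise a guide at 5 or more UMIs would count as present and cells with several targets would be kept. The second case applied. UMI counts were summed per target, arm and GEM group, which gave 8 sums per target, and tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood F test, GEM group as block) in R 4.3.3. Both arms of a comparison come from the same capture, so the GEM group pairs them by design. Genes with a mean of at least 10 counts over the sums were tested at a Benjamini-Hochberg adjusted p of 0.05, per target for all genes and over 17 pairs for the named genes. Cells were not treated as replicates. Standard errors were derived from the fold change and its F statistic. CPM were computed from the summed gene UMIs of each arm and GEM group.

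The matched comparison was added after the first values had been seen. A guide was present above the minimum of the histogram of guide UMIs of its GEM group (26, 8, 51 and 32 UMIs). Reference cells were drawn with a fixed seed to follow the distribution of targets per cell in the target cells. The highest numbers of targets were pooled into a single class, and a class with too few reference cells was left short. Gene lists were tested with camera from limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation, which had 3 residual degrees of freedom. The 20 gene lists and the cluster markers were fixed before the data were examined. Clusters were made with leidenalg 0.10.2 at resolution 0.5 from 2000 variable genes, 30 components and 20 neighbours, without XIST, chromosome Y genes and guides. Tables and figures used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.

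The genes named in the text are the genes that targets are named after, the called cis pairs, the genes with the largest changes for the 3 targets with most calls, and list members and cluster markers. Genes of the matched comparison outside these rules were named after their values were seen. Alternatives were DESeq2 1.42.0 and its size factors, no filter on low counts, no block, other guide minimums, non-targeting cells as reference, no filter on cells, vectors as replicates, and leaving out each GEM group. The tests were also run on simulated data, with a dispersion of 0.005 and with the same gene proportions in both arms apart from the changed genes. With 200 of 17960 genes changed in the matched KLF6 enhancer comparison, 75.8% of genes with a log2 fold of 0.5 and 95.9% of those with a log2 fold of 1 were recovered, with 18 false calls. With 200 of 22206 genes changed in the first KLF6 enhancer comparison, 65.7% and 84.0% were recovered, with 6 false calls. The simulated arms could not differ in targets per cell, so these false calls do not give the error rate of the real comparisons. In the real first comparison control targets gave 1350 to 4391 called genes.

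Non-targeting vectors compared with each other gave 170, 830 and 29 of 18599 genes called. The arms of that comparison were not matched on the number of targets per cell. Cells with a vector could also hold other non-targeting vectors, while their reference cells lacked that vector. The arms could therefore differ in targets per cell, so these counts do not give an error rate in the absence of any difference, nor that of the matched comparison.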

Results

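Single-cell transcriptomes and guide RNA sequences were measured in the same droplets of cultured human renal cortical epithelial cells, a primary culture of kidney tubule cells pooled from 4 donors. The cells carried dCas9 joined to the ZIM3 repressor domain, a CRISPR interference system that silences the element a guide RNA binds. The 4 captures (GEM groups 1 to 4) each gave 1 gene expression library and 1 guide library, and they are captures of the same pool, so the spread between them is mostly technical. The files held 9183, 9445, 7109 and 8016 cell barcodes with 380477568, 216029316, 110783404 and 280584503 gene UMIs (unique molecular identifiers, each counting 1 captured RNA molecule). Guide libraries held 28630798, 10420379, 44944982 and 31826169 UMIs. After removal of shallow cells and cells rich in mitochondrial RNA, 32176 cells remained, of which 26922 carried a guide.

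The library held 66 vectors with a pair of guides each, directed at 42 targets: 6 gene promoters, 7 enhancers named after a gene, 17 elements named after a human variant, and 12 controls (4 non-targeting, 4 gene desert and 4 closed chromatin sites near an enhancer). The non-targeting 2 control was not detected at 5 UMIs in a cell, which left 41 targets. Cells carried many targets at once: a guide-bearing cell held 5.48 ± 1.5 targets (SD, n = 4 GEM groups), and 20.8% ± 3.38 of these cells held a single target. Of the cells with enough guide UMIs, 23.8% ± 0.750 (SD, n = 4) were assigned to 1 target, below the 50% fixed before the data were examined for comparing singly assigned cells. Each target was therefore tested as cells with its guide against all guide-bearing cells without it.

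**Figure D1:**
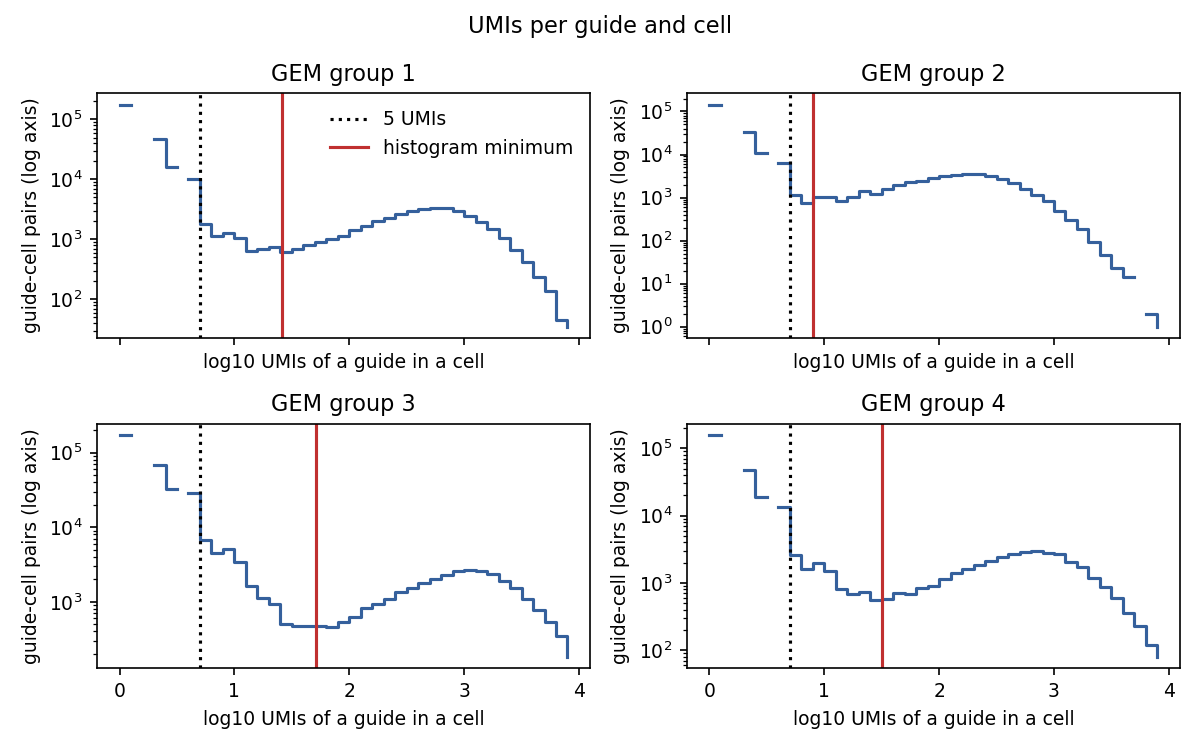
UMIs of a guide in a cell (log10, horizontal axis) against the number of guide-cell pairs (log axis) in each of the 4 GEM groups. The dotted line stands at 5 UMIs and the solid line at the minimum of the histogram, which lay at 26, 8, 51 and 32 UMIs.

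Because cells with a given guide at 5 UMIs also differed from the other cells in the number of targets they held, a second comparison was made for every target. It took a guide as present above the histogram minimum. Reference cells were drawn to have a like distribution of targets per cell, as far as the available cells allowed. Where too few cells without the target held a given number of targets, fewer were drawn. For the FTH1 enhancer, 4281 cells with the target were set against 4080 reference cells, so its matching was incomplete. This matched comparison was chosen after the first values had been seen, and both values are given for the named genes of promoters and enhancers.

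The promoter guides asked whether repression lowered the gene they were placed at. All 6 genes were lower in cells with their promoter guides, in all 4 GEM groups. CD55, a surface protein that protects cells from complement, fell by 1.08 on the log2 scale (SE 0.09), from 18.8 ± 0.775 to 8.96 ± 3.02 CPM (UMI counts scaled to the library total; SD, n = 4). NT5E, the ecto-enzyme that makes adenosine from AMP, fell by 1.05 (SE 0.04), from 111 ± 6.01 to 54.8 ± 8.88 CPM. ANPEP, a brush border aminopeptidase of proximal tubule cells, fell by 0.78 (SE 0.03), from 153 ± 5.67 to 89.5 ± 4.87 CPM. MAFF, a small MAF transcription factor, fell by 0.80 (SE 0.10), C15orf40 fell by 0.60 (SE 0.11) and FUBP1, a regulator of transcription and splicing that binds single-stranded DNA upstream of MYC, fell by 0.45 (SE 0.04).

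The adjusted p for these 6 genes ran from 1.74e-18 for NT5E to 7.48e-05 for C15orf40 (edgeR quasi-likelihood test, Benjamini-Hochberg over 17 named pairs), and all 6 also passed when adjusted over the list alone. In the matched comparison C15orf40 fell by 1.47 (SE 0.05), CD55 by 1.72 (SE 0.08), MAFF by 1.31 (SE 0.10), NT5E by 1.20 (SE 0.05), ANPEP by 0.81 (SE 0.04) and FUBP1 by 0.59 (SE 0.05). Of the 12 promoter guides, 10 were placed in annotated exons on GRCh38. Both CD55 guides lay in its 5' UTR on chromosome 1 (207321703 to 207321732) and both MAFF guides in its 5' UTR on chromosome 22 (38202084 to 38202129). ANPEP had a guide in its 5' UTR on chromosome 15 (89814809 to 89814828) and another in coding exon 2 (89806569 to 89806588).

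The enhancer guides asked whether silencing a distal element lowered the gene it was named after. In the first comparison 6 of 7 genes were lower. FTH1, the heavy chain of the iron store ferritin, fell by 0.39 (SE 0.03), from 19960 ± 696 to 15170 ± 994 CPM (SD, n = 4 GEM groups). LGALS3, which codes for the galactose-binding lectin galectin-3, fell by 0.55 (SE 0.05), and PLIN3, a coat protein of lipid droplets, by 0.53 (SE 0.03). TKT, an enzyme of the pentose phosphate pathway, fell by 0.36 (SE 0.05). The lysosomal protease CTSB fell by 0.29 (SE 0.06) and the transcription factor KLF6 by 0.16 (SE 0.03), but KLF6 stood at +0.07 against cells with only non-targeting guides.

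Adjusted p values of the 6 genes ran from 2.33e-12 for PLIN3 to 0.0003 for CTSB (edgeR quasi-likelihood, Benjamini-Hochberg over 17 named pairs). CSTB, an inhibitor of cathepsins, had a log2 fold change of -0.08 (SE 0.05, edgeR adjusted p = 0.139) and was lower in 3 of 4 GEM groups, with +0.02 at 3 guide UMIs and +0.03 against cells with only non-targeting guides. In the matched comparison all 7 passed: LGALS3 fell by 0.84 (SE 0.03), CTSB by 0.75 (SE 0.03), PLIN3 by 0.69 (SE 0.03), FTH1 by 0.61 (SE 0.03), KLF6 by 0.39 (SE 0.03), TKT by 0.38 (SE 0.03) and CSTB by 0.30 (SE 0.02). FTH1 has near-identical processed copies in the genome, so its counts are uncertain to the extent that reads were split among them.

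Guides at closed chromatin near 4 of these enhancers gave the background. In the first comparison 3 of 4 pairs passed the test, with FTH1 at +0.21 (SE 0.05), KLF6 at +0.16 (SE 0.04) and PLIN3 at -0.08 (SE 0.03). In the matched comparison 0 of 4 passed with edgeR or DESeq2 and 0 of 4 had an unadjusted edgeR p below 0.05, with log2 fold changes of -0.00 for FTH1, -0.00 for TKT, -0.07 for PLIN3 and 0.06 for KLF6. A second draw of reference cells passed 1 of 4.

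**Figure D2:**
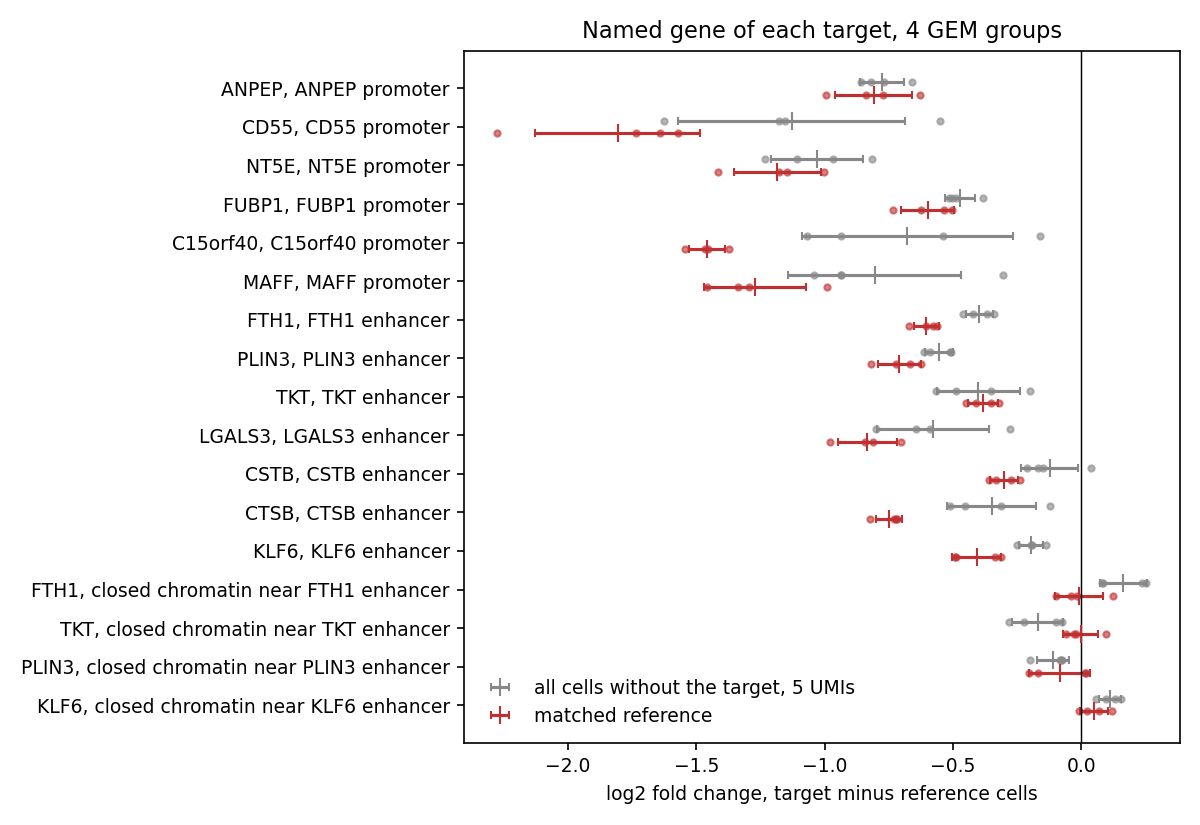
Log2 fold change of each target's named gene (horizontal axis) in 4 GEM groups (points) with their mean and SD (bars), against all cells without the target (grey) and against the matched reference (red). The 13 promoter and enhancer genes lie below 0 in the matched comparison, and the 4 closed chromatin pairs lie around 0.

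Other genes within 1 Mb of the named gene of each of the 17 pairs were tested in the matched comparison. Of 430 target-gene pairs, 1 passed: BEST1, a chloride channel gene best known from the retinal pigment epithelium, fell by 0.67 (SE 0.06) with FTH1 enhancer guides, from 14.1 ± 1.91 to 9.04 ± 1.60 CPM (edgeR quasi-likelihood adjusted p = 2.99e-07, Benjamini-Hochberg over 430 pairs, lower in 4 of 4 GEM groups). Its annotated span on chromosome 11 (61949821 to 61965515) overlaps that of FTH1 (61959718 to 61967660), which lies on the opposite strand. Whether reads of FTH1 were counted for BEST1 was not tested.

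The variant elements asked which genes respond where a human variant lies in a regulatory site. The genes given here are examples singled out after their values were seen, all passing the matched test in both draws and lying outside the range of the other 40 targets. NDRG1, a gene induced by hypoxia and differentiation, fell by 0.72 (SE 0.04) with rs10283362 guides, from 76.6 ± 2.23 to 46.3 ± 4.59 CPM (SD, n = 4; edgeR quasi-likelihood adjusted p = 4.52e-09, lower in 4 of 4 GEM groups), and over the other targets it ranged from -0.14 to 0.11. RBPMS, an RNA-binding protein gene, fell by 0.28 (SE 0.02) with rs2979488 guides, from 323 ± 11.3 to 264 ± 9.11 CPM (edgeR adjusted p = 9.05e-07). With the same guides the metallothionein gene MT1X rose by 0.18 (SE 0.02). PLCB4, a phospholipase C gene, fell by 0.19 (SE 0.01) with rs527616 guides (edgeR adjusted p = 6.28e-07). RHEX fell by 0.15 and the long non-coding RNA AL138828.1 rose by 0.26 with rs16874072 guides, and L3MBTL4 fell by 0.20 with rs4720089 guides. AL138828.1 was also among the leading genes of cluster 5 of the cells (349.8 against 55.89 CPM in the other cells). Reference cells were not matched on cluster or donor, so a shift in the mix of cells was not separated from a response. NDRG1 and RBPMS lie on chromosome 8 (133237171 to 133302022 and 30384479 to 30572261), and the variant elements were not placed on the genome here, so distances are not given.

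The transcriptome-wide test asked which targets changed genes beyond their own. In the first comparison a median of 3395 of 22215 genes passed per tested target (1711 to 6989), and the 11 control targets gave a median of 2568 (1350 to 4391). The 7 enhancers and 17 variant elements had 14 and 34 vectors, against 4 vectors for the 4 targets of each control class. Counts of calls were thus not compared at equal numbers of cells. The most calls came with rs2823139 (6989), rs10224210 (6386) and rs527616 (5781) guides, and the most frequent guide of each was found in 5813, 5022 and 4197 cells. CST1, a secreted inhibitor of cysteine proteases, had the lowest value with each of these 3 targets (log2 fold changes of -5.14, -7.30 and -4.98 in that order), and LINC02548 was also lower with each. ECEL1 and LINC01478 were higher with each of the 3, ECEL1 by 1.39, 1.34 and 1.46. The keratin gene KRT81 fell by 3.27 (SE 0.22) with rs527616 guides and IGFBP1, a binding protein of insulin-like growth factors, rose by 1.75 (SE 0.22) with rs2823139 guides. Most of the genes with the largest changes had mean counts of 10 to 40. With matched cells CST1, LINC02548 and ECEL1 fell under the count minimum for the 3 targets and were not tested. KRT81 stood at -3.41 (edgeR adjusted p = 0.00578) and at -2.25 in a second draw, where it did not pass. IGFBP1 stood at 1.17 (edgeR adjusted p = 0.781), and LINC01478 at 2.12 with rs2823139 and at -2.81 with rs527616 guides, neither passing. Without the GEM group as a block the medians were 758 for tested and 648 for control targets, and without GEM group 4 they were 1723 and 1013.

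In the matched comparison the median fell to 7 genes for tested targets (0 to 181) and to 3 for control targets (0 to 16). Numbers of cells still differed, with 4281 holding FTH1 enhancer guides, 1217 MAFF promoter guides and 1111 guides at closed chromatin near the KLF6 enhancer. The targets with more calls than any control were the KLF6 enhancer (181 genes), the MAFF promoter (53), the FUBP1 promoter (51), the FTH1 enhancer (40), rs2979488 (30), rs16874072 (18) and rs527616 (17). In a second draw the highest control was gene desert 3 with 17 genes, and rs2979488 (16), the MAFF promoter (12) and rs527616 (10) lay below it. The highest control had 37 genes without GEM group 1 (FUBP1 promoter 29, MAFF promoter 10), 54 without GEM group 4 (FTH1 enhancer 47, MAFF promoter 50) and 4 without the block, where the highest tested target had 3. Guides at rs11154336 and gene desert 4 gave 0 calls with edgeR, with 801 and 839 genes at an unadjusted p below 0.05.

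**Figure D3:**
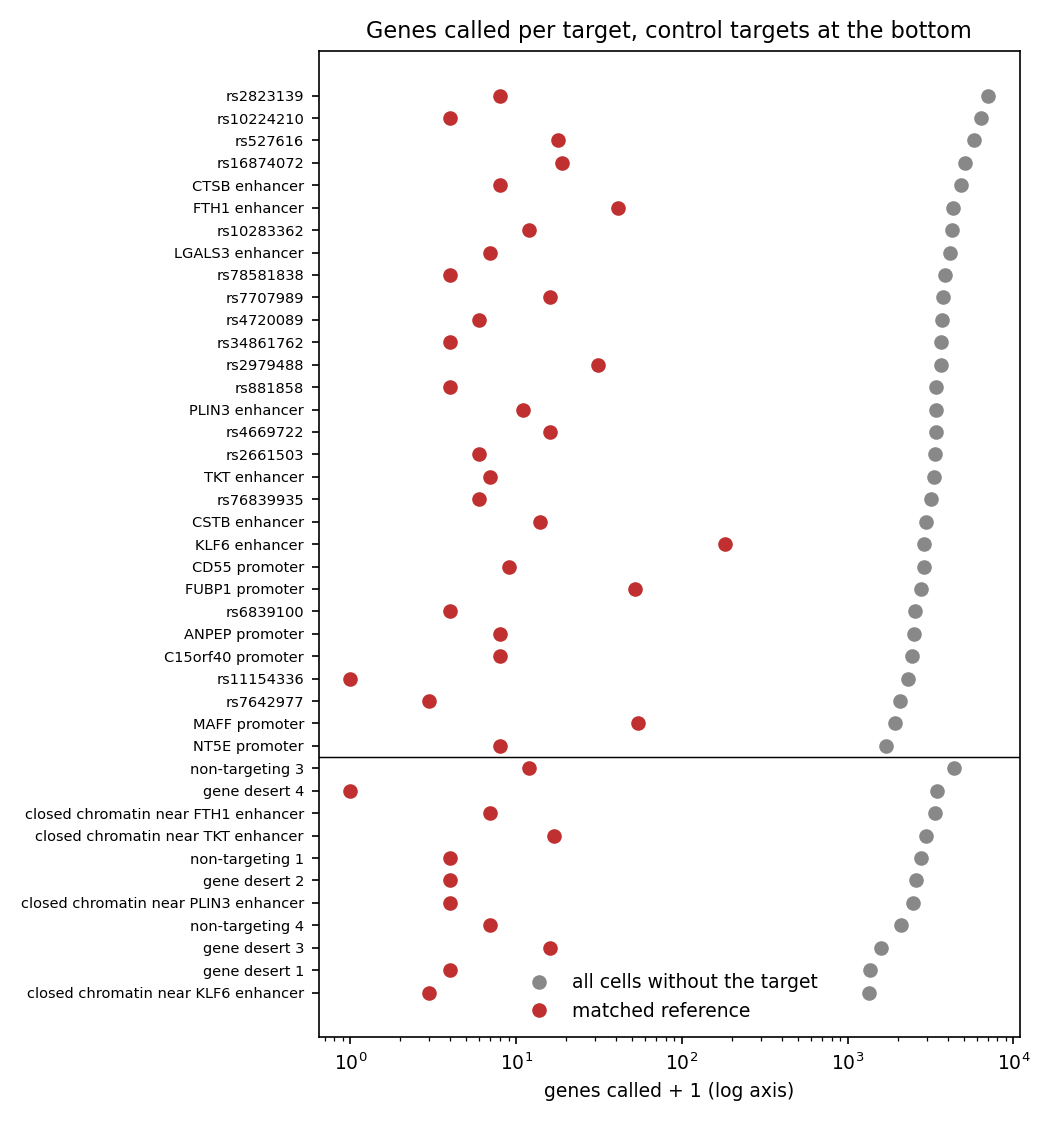
Genes called per target plus 1 (log axis) against all cells without the target (grey) and against the matched reference (red), with the 11 control targets under the line. Grey points lie between 1350 and 6989 genes, and red points between 0 and 181.

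With KLF6 enhancer guides, 115 genes fell and 66 rose in the matched comparison. LGALS1, which codes for galectin-1, fell by 0.23 (SE 0.02), TMSB10, an actin-binding thymosin, by 0.15 (SE 0.02), S100A10 by 0.18, ANXA1 by 0.18, ANXA2 by 0.13 and ACTB by 0.10. The microtubule-associated genes DCLK1 and MAP1B fell by 0.58 (SE 0.06) and 0.24 (SE 0.02). FN1, a matrix glycoprotein, rose by 0.20 (SE 0.02), and APOE, a lipid carrier, by 0.23 (SE 0.02). These genes were named after their values were seen, and each passed with an edgeR adjusted p of 0.0104 or below, in the same direction in 4 of 4 GEM groups. APOE was also among the leading genes of cluster 3 (708.5 against 213.2 CPM in the other cells), and reference cells were not matched on cluster.

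Among the lists fixed before the data were examined, 11 of 28 cytosolic ribosomal protein genes rose with KLF6 enhancer guides and 27 did when adjusted over the list alone (RPS3 by 0.09, SE 0.02). A shift of this list was not particular to these guides. With camera at the preset correlation it was called with 29 targets in the matched comparison, 8 of them controls, higher with 18 and lower with 11. Metallothionein genes went both ways, with 3 of 8 higher and 1 lower (MT1G by +0.33, MT1X by +0.14, MT1M by -0.18), and 2 of 8 passed in a second draw, in which MT1G did not. In the interferon list, 3 of 21 genes fell, among them IFIT2 by 0.40 (SE 0.08) and IFIT3 by 0.20 (SE 0.03), but IFIT2 did not pass in a second draw (-0.14), and the 2 stood at +0.15 and +0.09 against all cells without the target. The gene desert 2 control also had 3 of 21 interferon genes called. IFIT2 and IFIT3 were also among the leading genes of cluster 5, on which reference cells were not matched. BIRC3, an inhibitor of apoptosis induced by NF-kB, fell by 0.26 (SE 0.04). The count of 181 genes was 310 in a second draw, 144 with DESeq2, 55, 109 and 79 without GEM groups 1, 2 and 4, and 2 without the GEM group as a block.

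With FUBP1 promoter guides, 5 of 22 cell division genes rose in the matched comparison and 17 did when adjusted over the list alone. AURKA, a mitotic kinase, rose by 0.50 (SE 0.08), TPX2, its activator on the spindle, by 0.46 (SE 0.08), CCNB1, the mitotic cyclin B1, by 0.51 (SE 0.10), BIRC5 by 0.66 (SE 0.14) and RRM2, a subunit of ribonucleotide reductase, by 0.65 (SE 0.13). TK1, the thymidine kinase of dividing cells and not a member of the list, rose by 0.86 (SE 0.12). The median of the list, 0.51, was the highest of the 41 targets and the other 40 reached 0.23, while in a second draw it was 0.37 against 0.34. These genes move together with the share of dividing cells (MKI67 at 247.2 CPM in cluster 6 against 7.618 in the other cells). Reference cells were not matched on cluster or donor, so the 17 members do not count as separate findings. With camera at the preset correlation the list was called with 29 targets, 7 of them controls. Outside the cell division list, the nuclear long non-coding RNA NEAT1 fell by 0.28 (SE 0.03), the adhesion gene CDH6 by 0.16 (SE 0.03), and the interferon-induced IFI27 rose by 0.35 (SE 0.05). Against all cells without the target these 6 genes had the opposite sign, with AURKA at -0.15, TPX2 at -0.23, CCNB1 at -0.17, BIRC5 at -0.28, RRM2 at -0.27 and TK1 at -0.05. The count of 51 genes was 17 with DESeq2, 29 and 18 without GEM groups 1 and 3, and 1 without the block.

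With FTH1 enhancer guides, genes other than FTH1 changed, of which TFRC, HMOX1 and SQSTM1 were named after their values were seen. TFRC, the transferrin receptor that imports iron, fell by 0.28 (SE 0.03), from 74.0 ± 1.31 to 60.9 ± 3.82 CPM (SD, n = 4; edgeR adjusted p = 4.86e-05). HMOX1, which codes for heme oxygenase, rose by 0.25 (SE 0.04), and the autophagy receptor SQSTM1 by 0.18 (SE 0.03), but with vectors as replicates HMOX1 stood at -0.041. The fit with vectors also differed in guide minimum and reference and was not matched, so the difference cannot be laid to the vectors alone. In the hypoxia list 3 of 20 genes fell and 14 did when adjusted over the list alone: the glucose transporter SLC2A1 fell by 0.20 (SE 0.04), PFKFB3 by 0.15 (SE 0.03) and LDHA by 0.12 (SE 0.02), the latter 2 acting in glycolysis. With camera at the preset correlation the hypoxia list was lower with 11 targets and higher with 3, 2 of the 14 being controls. In the cell division list 3 of 22 fell (TOP2A by 0.29, CENPF by 0.26, NUSAP1 by 0.24) and 13 did when adjusted over the list alone, while 0 of 22 passed in a second draw and CENPF stood at 0.0042 with vectors as replicates. In the p53 list MDM2 rose by 0.13 (SE 0.02). PFKFB3, SLC2A1, TOP2A, CENPF, NUSAP1 and MDM2 moved the same way in cells with 7 or more targets against 1 or 2. Whether incomplete matching on targets per cell contributed was not tested. The count of 40 genes was 83 in a second draw, 22 with DESeq2, 73, 20 and 26 without GEM groups 1, 2 and 3, and 2 without the block.

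With MAFF promoter guides PTPN3, a tyrosine phosphatase gene, fell by 0.42 (SE 0.04), and the brush border peptidase gene ENPEP rose by 0.36 (SE 0.04). CYP3A5, a drug-metabolizing enzyme of proximal tubule, rose by 0.24 (SE 0.05). In the cell division list 1 of 22 genes fell, and 16 did when adjusted over the list alone, while 0 of 22 passed in a second draw. The count of 53 genes was 12 in a second draw, 11 with DESeq2, 10 and 28 without GEM groups 1 and 3, and 3 without the block. Single genes stood out with other targets in the matched comparison: FABP5, a fatty acid carrier, fell by 0.40 (SE 0.03) with PLIN3 enhancer guides, SNF8 by 0.37 (SE 0.03) with CD55 promoter guides, VEGFB by 0.35 (SE 0.04) with CSTB enhancer guides and the collagenase MMP1 by 0.62 (SE 0.09) with ANPEP promoter guides. SFRP1, a WNT antagonist, rose by 0.61 (SE 0.08) with NT5E promoter guides. It was also among the leading genes of cluster 10 (370 against 28.0 CPM in the other cells), and reference cells were not matched on cluster or donor. The 6 promoter targets, MAFF and FUBP1 included, had a single vector each, so no other vector repeats the changes seen with them.

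**Figure D4:**
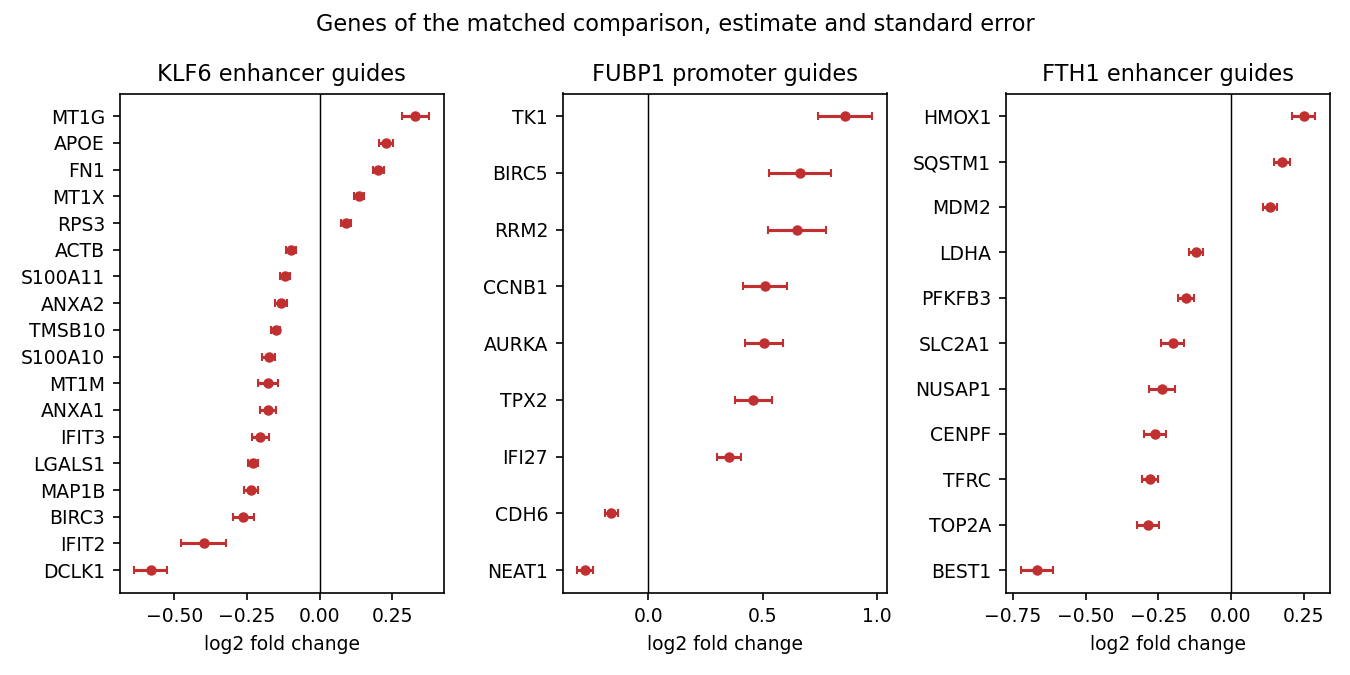
Log2 fold change (horizontal axis) of genes other than the named gene with KLF6 enhancer, FUBP1 promoter and FTH1 enhancer guides in the matched comparison, as estimate and standard error over 4 GEM groups. The cell division genes named in the text lie between 0.46 and 0.86 with FUBP1 promoter guides, the highest being TK1, which is not in the fixed list. TFRC lies at -0.28 with FTH1 enhancer guides.

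Gene lists were tested per target with camera, and no list passed for any target with an estimated correlation, so the calls here depend on a preset one. The estimate had 3 residual degrees of freedom and could miss a broad change, so its lack of calls does not decide either way. Between cells with 7 or more and with 1 or 2 targets, 21 of 22 cell division genes fell. Even so, that list had an adjusted p = 0.324 (camera, estimated correlation). In the first comparison cell division, cholesterol synthesis and renal epithelial identity genes were lower with all 41 targets, and p53 and unfolded protein response genes were higher with all 41. The 41 comparisons share most of their cells, so this agreement does not count as 41 separate findings. Against matched cells the cell division list was higher with 12 targets and lower with 17, 7 of the 29 being controls. Of the target-list pairs, 336 of 600 passed for tested and 117 of 220 for control targets. In the matched comparison 176 of 575 and 59 of 209 passed. With an estimated correlation 0 of 600 and 0 of 220 passed in the first comparison, with a lowest adjusted p = 0.291 and with 106 and 30 pairs at an unadjusted p below 0.05. The matched comparison also gave 0 of 575 and 0 of 209, at a lowest adjusted p = 0.609, with 37 and 10 pairs at an unadjusted p below 0.05. Thus the list calls of KLF6, FUBP1, FTH1 and MAFF targets rest on the counts of members and not on this test. Members of a list can move together, so these counts are not numbers of separate findings.

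The cells resembled tubule epithelium with features of injured tubule. The injured tubule list summed to 12208 ± 609 CPM (SD, n = 4), led by the secreted phosphoprotein SPP1 at 6223 ± 435 CPM and the intermediate filament gene VIM at 2474 ± 193 CPM. The kidney lineage factor PAX8 stood at 285 ± 10.1 CPM. The zinc-binding metallothioneins summed to 23600 ± 701 CPM, of which MT2A gave 17769 ± 563 CPM. Proximal tubule genes summed to 923 ± 18.6 CPM, loop of Henle genes to 191 ± 3.45 CPM and distal and collecting tubule genes to 126 ± 5.61 CPM, while the sodium-phosphate cotransporter SLC34A1 stood at 0.109 ± 0.0182 CPM. Fibroblast genes summed to 113 ± 3.77, immune genes to 70.0 ± 0.987, podocyte genes to 31.1 ± 1.20 and endothelial genes to 2.31 ± 0.140 CPM.

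Clustering of the 32176 cells gave 14 clusters. Clusters 6 (7.42% ± 0.407 of cells; SD, n = 4) and 12 (1.28% ± 0.121) were dividing cell-like, with 8 of 8 markers raised, among them MKI67, TOP2A and CENPF. Cluster 4 (9.88% ± 0.280) was loop of Henle-like with 4 of 6 markers raised, and cluster 7 (6.30% ± 0.419) was proximal tubule-like with 3 of 10. Cluster 10 (3.48% ± 0.166) was led by SLC12A3, the thiazide-sensitive cotransporter of the distal tubule, at 168 against 3.51 CPM in the other cells, and cluster 11 (1.85% ± 0.187) by LCN2 and the kallikrein genes KLK6 and KLK7. Cluster 13 (0.396% ± 0.0379) was led by FLG and PTGDS and was fibroblast-like, with 5 of 7 markers raised, while 2 of 5 podocyte markers were also raised. Loop of Henle markers were raised outside cluster 4 too, 4 of 6 in the dividing cluster 12 and 3 of 6 in cluster 9. Clusters can follow donors, which are not labelled per cell.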

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

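All tests of explanations in this part had their bounds written after the results they measure had been seen. The counts over other splits of the 8 sums were also recorded after the counts were known. The GEM group pairs the sums, so each real split was set against the 8 splits that part all 4 pairs, too few for a share under 5%.

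Of 85 values compared over the 4 GEM groups, 5 had 1 GEM group far from the other 3 by the share of the range that the gap to the nearest takes, and chance gives about 1 in 20. GEM group 1 had 98 barcodes under the UMI minimum against 44 to 52 in the others. MAFF in cells with its promoter guides at 5 UMIs stood at -0.30 in GEM group 3 against -1.04 to -0.94 in the others. PLIN3 with the closed chromatin guides near its enhancer stood at -0.20 in GEM group 2 against -0.08 to -0.07 in the others, before matching. CTSB with its enhancer guides in the matched comparison stood at -0.82 in GEM group 1 against -0.73 to -0.72 in the others. Guide-bearing cells with at most 1 dCas9 UMI made up 17.0% in GEM group 3 against 8.45% to 9.78% in the others.

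A signal was also present in data outside the comparisons. Cells without a guide, left out of every comparison, held 563 ± 70.0 CPM of dCas9 (SD, n = 4 GEM groups) against 1644 ± 148 in cells with a guide, and 56.3% ± 3.98 of them had at most 1 dCas9 UMI against 11% ± 4.04.

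The first pattern is that control guides gave a median of 2568 called genes in the first comparison. Matching reference cells on UMIs per cell left a median of 2903 for control targets, which argues against depth as the cause, and cells with 8 or more targets held 1.26 ± 0.2 times the median UMIs of cells with 1 target (SD, n = 4; 1.07 to 1.54), which passed the 1.5 set for doublets in 1 GEM group and leaves doublets open. Matching on the number of targets per cell gave a median of 9, so the number of targets a cell holds is a candidate cause, found and tested on the same data. The counts of 6989 genes with rs2823139, 6386 with rs10224210 and 5781 with rs527616 guides were each reached by 1 of 8 splits, the real one, with 0 genes as the highest of the others for each. No biological explanation for this pattern was tested.

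The second pattern is that guides a and b of different vectors met in 1 cell. Among cells with exactly 2 guides above the histogram minimum, 66.3% ± 0.943 (SD, n = 4) held the pair of 1 vector and 29.7% ± 0.610 held guide a of a vector and guide b of another. Loss of a guide from each of 2 vectors predicts far fewer such pairs, and the observed numbers were at least 16.8 times those expected. Such a-b pairs made up at least 86.8% of pairs from different vectors, against 50% without regard to position, which recombination between vectors may explain, and whether it arose in the virus, in the cells or in the library amplification was not tested. No biological explanation was tested.

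The third pattern is that genes other than FTH1 changed with FTH1 enhancer guides, with TFRC, SLC2A1, PFKFB3 and LDHA lower and HMOX1 higher, although HMOX1 stood at -0.041 with vectors as replicates and no matching. The FTH1 counts that were lost shift every other gene by 0.011 on the log2 scale, too little for these changes. A candidate explanation is more free iron, since iron lowers TFRC RNA and feeds the enzymes that degrade hypoxia-inducible factors. Lower hypoxia genes were not particular to FTH1 enhancer guides, since the list was lower with 11 targets (camera, preset correlation, matched comparison). Between cells with 7 or more and with 1 or 2 targets, 7 of 20 hypoxia genes also fell and 2 rose. PFKFB3 (-0.32) and SLC2A1 (-0.14) were among those that fell. Matching on targets per cell was incomplete for FTH1 enhancer guides, and whether a remaining difference contributed was not tested. NRF2 targets other than HMOX1 and SQSTM1 had a median of 0.0625, highest of 41 targets in 1 draw and second highest in the other. Of these, 0 of 18 passed in either, which leaves the reading of more free iron open. The count of 40 genes was reached by 1 of 8 splits, with 5 as the highest of the others.

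Among the other counts of the matched comparison, the 181 genes with KLF6 enhancer guides were reached by 1 of 8 splits, with 5 as the highest of the others. The 51 genes with FUBP1 promoter guides and the 53 genes with MAFF promoter guides were also reached by 1 of 8, with 0 and 8 as the highest. Over all 32 splits that could be fitted, most of which mix the pairs, the highest of the others were 24 for KLF6, 66 for FUBP1 and 53 for MAFF targets.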

How the results depend on the processing

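The alternatives with a guide minimum at the histogram minimum, with a matched reference, or with both were chosen after seeing the data, and the others were planned. All 6 promoter genes were called lower under all 25 settings. Of the 13 promoter and enhancer genes, 12 were called lower at first and 10 to 13 under the alternatives, the lowest count coming with cells holding only non-targeting guides as reference and 11 with a minimum of 3 guide UMIs. Without the GEM group as a replicate block the same count of 12 was called. Over all settings, the 17 named pairs gave 340 values with the same direction and call, 32 that lost and 21 that gained the call, and 11 reversed. CSTB stood at 0.021 with 3 guide UMIs and at 0.034 against non-targeting cells, and KLF6 at its enhancer at 0.069 against non-targeting cells. Of the closed chromatin pairs, PLIN3 stood at 0.015 with 3 guide UMIs, FTH1 in the matched comparison at -0.0020 with edgeR, at -0.00070 with DESeq2 and at -0.049 without replicate 4, and TKT at 0.035 with a matched number of targets alone and, in the matched comparison, at 0.0095, 0.018 and 0.0048 without replicates 1, 2 and 3. The cause was not tested.

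Closed chromatin pairs called fell from 3 to 0 with a matched number of targets alone (1 at an unadjusted p below 0.05, edgeR). They fell to 0 in the matched comparison with edgeR, DESeq2 or no block (0 at an unadjusted p below 0.05 in each), and to 1 in a second draw. Without a replicate they ran from 2 to 4 in the first comparison and from 0 to 1 in the matched one.

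Median calls per tested target moved from 3395 to 758 without the block, 5675 with 3 guide UMIs and 1834 against non-targeting cells. They were 967.5 with the histogram minimum and non-targeting cells, and 23.5 with matched targets alone. In the latter the highest tested target had 2761 calls and the highest control 14. The matched comparison gave 7, its second draw 8, DESeq2 there 3 and no block there 0 (427.5 at an unadjusted p below 0.05, edgeR). With vectors as replicates the median was 0.5, which rests on few vectors per target. Leaving out a replicate gave 1723 to 2874.5, and 11.5 to 13 in the matched comparison. For control targets 2568 became 648, 5948, 1603 with the histogram minimum, 895, 9, 3, 5, 1 with DESeq2 and 0 with no block (432 at an unadjusted p below 0.05), and 1013 to 2315 or, matched, 5 to 10 without a replicate.

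Target-list pairs called moved from 336 to 0 with an estimated correlation (106 at an unadjusted p below 0.05 with camera), 176 in the matched comparison, 169 in its second draw, 83 with no block, 0 with an estimated correlation there (37 at an unadjusted p below 0.05), and 146, 179, 189 and 195 matched without replicates 1 to 4, against 321 to 353 unmatched. For control targets 117 became 0 (30 at an unadjusted p below 0.05), 59, 61, 27, 0 (10 at an unadjusted p below 0.05) and 52, 48, 55 and 60, against 107 to 122 unmatched.

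In the matched comparison, 181 genes with KLF6 enhancer guides became 310 in the second draw, 2 with no block and 55, 109, 178 and 79 without replicates 1 to 4. With FUBP1 promoter guides 51 became 17 with DESeq2, 1 with no block and 29, 40, 18 and 65 without a replicate. With FTH1 enhancer guides 40 became 83, 22 with DESeq2, 2 with no block and 73, 20, 26 and 47. With MAFF promoter guides 53 became 12, 11 with DESeq2, 3 with no block and 10, 43, 28 and 50. Removing the block left the pairing of arms within a capture unused, and the cause of the lost calls was not tested further. Of the genes named there, 385 values kept direction and call, 194 lost the call and 15 reversed. The reversals against all cells without the target at 5 guide UMIs were S100A11 at 0.027, IFIT2 at 0.15 and IFIT3 at 0.094 with KLF6 enhancer guides, and AURKA at -0.15, TPX2 at -0.23, CCNB1 at -0.17, BIRC5 at -0.28, RRM2 at -0.27 and TK1 at -0.050 with FUBP1 promoter guides. With the histogram minimum alone IFIT2 stood at 0.012, CCNB1 at -0.00078 and RRM2 at -0.071, with matched targets alone IFIT2 stood at 0.044, and with vectors as replicates HMOX1 stood at -0.041 and CENPF at 0.0042 with FTH1 enhancer guides.

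Cells assigned to 1 target moved from 23.8% to 38.2% at 3 UMIs and a share of 60%, to 18.7% at 10 UMIs and a share of 90%, and to 27.0% with the histogram minimum, and targets per cell from 5.48 to 8.01 and 3.91. Clusters numbered 9 at resolution 0.3. Over all barcodes, summed CPM moved by more than 1 SD to 195 for loop of Henle, 2777 for renal epithelial identity, 1621 for p53, 1247 for unfolded protein and ATF4, 982 for cholesterol synthesis and 33.4 for podocyte genes. The window of 0.2 Mb was not run, since the elements were not placed on the genome.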

Other observations

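The tests of this part were all chosen after the results were seen.

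Cells with many targets differed from cells with few in genes of growth, stress and cell type. Targets were counted here at 5 guide UMIs, below the histogram minimum, and in GEM group 3 the mean number fell from 7.65 to 3.78 at that minimum. Cells with 7 or more targets were compared with cells with 1 or 2, and 8619 of 20780 genes passed, 4565 higher and 4054 lower (edgeR quasi-likelihood, Benjamini-Hochberg). Of 22 cell division genes 21 fell, also 21 when adjusted over the list alone, with MKI67 lower by 1.21 on the log2 scale, its level being 14.1 ± 1.68 against 33.8 ± 3.02 CPM (SD, n = 4 GEM groups). Of 20 p53 genes 18 rose, also 18 when adjusted over the list alone, among them the cell cycle inhibitor CDKN1A by 0.60 (SE 0.03), the stress cytokine GDF15 by 0.63 (SE 0.04) and the p53 antagonist MDM2 by 0.45 (SE 0.04). Of 20 unfolded protein and ATF4 genes 11 rose and 1 fell, with CHAC1 up by 0.95 (SE 0.07) and DDIT3 by 0.83 (SE 0.04). Of 20 cholesterol synthesis genes 13 fell, among them HMGCS1 by 0.55 (SE 0.05), and 25 of 28 ribosomal protein genes rose. Cell type markers moved too, with 11 of 20 renal epithelial identity, 12 of 18 injured tubule, 9 of 20 proximal tubule and 6 of 8 loop of Henle genes lower against 1, 3, 4 and 1 higher, and with 11 of 22 interferon genes higher and 4 lower. With an estimated correlation the lists had an adjusted p = 0.324 or above (camera). Cells with 8 or more targets also had more UMIs and a lower mitochondrial share than cells with 1 target in all 4 GEM groups. In GEM group 1 the medians were 46137 against 37062 UMIs and 6.91% against 7.58%. Viral load, guide number, cell type, cell state, depth, mitochondrial share and doublets were not separated here.

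Clusters also differed in the number of targets at 5 guide UMIs. Guide-bearing cells held 7.64 targets in cluster 5, which was led by IFIT2 and OLAH among annotated genes, and 8.40 in cluster 8, against 3.46 in the dividing cluster 12 and 4.34 in the dividing cluster 6. Few targets were not particular to dividing clusters, since cluster 3, with 0 of 8 dividing cell markers raised, held 4.10.

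Repression of the named genes was compared between cells with more and less dCas9 RNA. Over 13 promoter and enhancer pairs the mean log2 fold change was -1.16 in cells with at most 1 dCas9 UMI and -0.82 in cells with 2 or more, a mean difference of 0.34 (SD 0.552, exact two-sided permutation p = 0.042), and 3 of 13 pairs were lower with 2 or more UMIs. The median difference was 0.18. Cells with the target and at most 1 dCas9 UMI numbered 49 to 174 per pair, and the largest difference, for MAFF (-2.78 against -1.17), rests on 49 of them. The depth of the cells was not matched in this comparison. Counts were pooled over the GEM groups, and the pairs share most of their reference cells, while the permutation takes them as separate. Log ratios from few UMIs can also lean low. The p therefore does not measure an effect of dCas9.

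The vectors at the FTH1 enhancer differed. FTH1 stood at -1.30 with the first vector in 1124 cells and at -0.34 with the second in 3401 cells, for which guide b was not detected.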
